A study of Danio rerio with 5 samples.

How the data were processed

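Circular RNAs (circRNAs) were measured in 5 libraries of ribosomal RNA-depleted total RNA from whole zebrafish embryos, 1 library for each of 5 developmental stages, sequenced on an Illumina HiSeq instrument per the labels. A circRNA is recognised by reads that cross its back-splice junction, where a downstream position is joined to an upstream one. The ages were 4.5 hours post fertilization (hpf, blastula), 8 hpf (gastrula), 24 hpf (segmentation), 48 hpf (the stage the labels call throat) and 72 hpf (the stage the labels call incubation). Groups were taken from the labels, and no stage had a replicate.

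Each library's deposited table gave the chromosome, start and end of each circRNA with its count of junction reads, as whole numbers that had not been normalized. The lowest count listed was 2 reads, so a circRNA that was not listed was taken to have fewer than 2. Whether the caller left out junctions for other reasons is not given in the sources used here. A deposited series table gave, for the 1829 circRNAs listed in at least 2 libraries, the counts and a score that the authors scaled to library depth, named SRPBM in the file headers. All counts of the series table equalled those of the library tables, with 0 mismatches. Within a library, SRPBM was the junction read count times 1 constant. Read as reads per 1e+09, the constants gave denominators that were whole multiples of 150. Divided by 150, they gave 66.0, 76.5, 64.7, 65.5 and 54.5 megaunits of depth at 4.5, 8, 24, 48 and 72 hpf, a megaunit being 1e+06 such units. Whether a unit is a read or a read pair is not given in the sources used here. BWA 0.7.5a-r405 and edgeR 3.12.1 are named in the submitters' processing notes, without their roles. The circRNA caller and the genome build are not given in the sources used here, and coordinates are printed as the deposited tables give them.

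Counts were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, TMM factors came from edgeR 4.0.16 in R 4.3.3, and plots were drawn with matplotlib 3.10.9. A circRNA was counted as detected where it was listed. The number expected at the smallest junction read total was the hypergeometric expectation of circRNAs with at least 2 reads. The number expected at the lowest depth was the binomial expectation of the same. A circRNA was shared where chromosome, start and end were identical. The span was the distance from start to end in the genome, introns included. Medians carry order-statistic intervals, and shares carry exact Clopper-Pearson intervals, both at 95%. Intervals on medians and on shares of circRNAs treat circRNAs as independent units, and those on ratios and shares of reads treat reads as independent. Reads without molecular identifiers are not independent molecules, so intervals based on reads can be too narrow. No interval or bound covers variation between libraries of a stage.

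Abundance was compared between consecutive stages as the ratio of junction reads per depth, later over earlier, with the exact conditional 95% interval of the ratio of a pair of Poisson counts. With 1 library per stage, no p-value was computed for a difference in abundance between stages, and no such difference between stages has a replicate check. A circRNA entered a comparison with at least 10 junction reads over both libraries and was called higher or lower at a ratio of 2 or more. A circRNA that was not listed in a library was set at 3 reads there, and its ratio is given as a bound ("at least"), which holds only if the junction was left out for too few reads and was not placed at another position. The bound is the ratio at that setting and not a 95% limit. For chromosome 6, 6817343 to 6833488, at 8 over 4.5 hpf, it was 252-fold, while the lower 95% limit used for ranking was 136-fold. The circRNAs named in the text were chosen by rule. They were the 10 higher and 10 lower ones per comparison whose interval bound nearest 1 lay farthest from 1, the 5 with most reads per library, and the 10 with the highest mean SRPBM among those listed in all 5 libraries. For the intervals of these comparisons, a circRNA that was not listed was set at 1 read, the most it can have. These intervals set that ranking, the calls whose interval excludes 1, and the check of named ratios under other scalings. The rule also asked for a host gene symbol, which was dropped because the tables used here pair no circRNA with a gene. Regions were made by merging overlapping circRNAs with spans of at most 50 kb. Regions, shared back-splice ends, and the circRNAs of the listing groups and stepwise courses were chosen for description after the values were seen.

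The procedure was tested on simulated data, with 200 circRNAs per comparison changed by known folds. Counts were drawn from Poisson distributions without variation between libraries, as the intervals assume, so this checks the calculation only. Whether an interval held the true ratio was counted before counts under 2 reads were removed. The intervals of circRNAs that were not listed in a library were therefore not tested. The intervals held the true ratio for 97.6% of 545 circRNAs in the comparison of 8 with 4.5 hpf, 96.6% of 386 in that of 24 with 8 hpf, 96.5% of 347 in that of 48 with 24 hpf, and 97.2% of 426 in that of 72 with 48 hpf. In the same order, 13.3%, 9.68%, 8.16% and 10.2% of unchanged circRNAs passed the size rule by counting error. Changes of 2-fold were recovered for 62.7%, 44.8%, 50.7% and 52.2% of circRNAs, and changes of 4-fold for 95.5%, 79.1%, 88.1% and 86.6%.

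The comparisons, the size rule, the rule for named circRNAs and most alternatives were fixed before the data were examined. The alternatives were a minimum of 5 reads, equal junction read totals, the series table, positions within 5 bases, weighting by reads, scaling to total junction reads or by TMM, a minimum of 20 reads, a ratio of 4, and an interval that excludes 1. Others were added after the data were seen: equal depth, leaving out the 24 hpf library or the scaffold KN150127.1, a comparison of 48 with 8 hpf, and shared ends with at least 5 reads or at equal numbers of circRNAs or junction reads, as means of 200 random draws. Planned comparisons of genomic class, host genes and the bases next to the junctions were not run, because no annotation or genome of the build of the tables was used here.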

Results

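Back-splice junction reads were counted in whole zebrafish embryos at 5 stages, with 1 library each at 4.5 hpf (blastula), 8 hpf (gastrula), 24 hpf (segmentation), 48 hpf (labelled throat) and 72 hpf (labelled incubation). The series addresses which circRNAs are present at each stage of development. The libraries held 20410, 24580, 9563, 15850 and 19036 junction reads in that order, on 9559 different circRNAs. Most circRNAs had few reads, and the median was 3 reads in every library. The share listed at exactly 2 reads, the lowest listed, was 31.7% at 4.5 hpf and 48.8% at 24 hpf. Every value below comes from 1 library, so differences between stages carry counting error only and have no replicate check.

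As deposited, the gastrula library listed most circRNAs and the segmentation library fewest. There were 2829 circRNAs at 4.5 hpf, 3045 at 8 hpf, 1834 at 24 hpf, 2547 at 48 hpf and 2252 at 72 hpf. Junction reads per megaunit of depth were 309 at 4.5 hpf, 321 at 8 hpf, 148 at 24 hpf, 242 at 48 hpf and 349 at 72 hpf. A few circRNAs held much of the signal in some libraries. The 2 most abundant circRNAs held 34.3% of the junction reads at 8 hpf, against 4.87% at 24 hpf and 6.09% at 4.5 hpf. At the depth of the shallowest library, the expected numbers were 2486, 2294.8, 1545, 2181.5 and 2252, with 4.5 hpf then highest and 24 hpf still lowest. The 8 hpf library was the deepest, at 76.5 megaunits, and with at least 5 reads it listed 801 circRNAs against 933 at 4.5 hpf. At equal junction read totals the order turned, with 1834 at 24 hpf against 1563.1, 1252.9, 1623.8 and 1178.8 at 4.5, 8, 48 and 72 hpf.

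**Figure D1:**
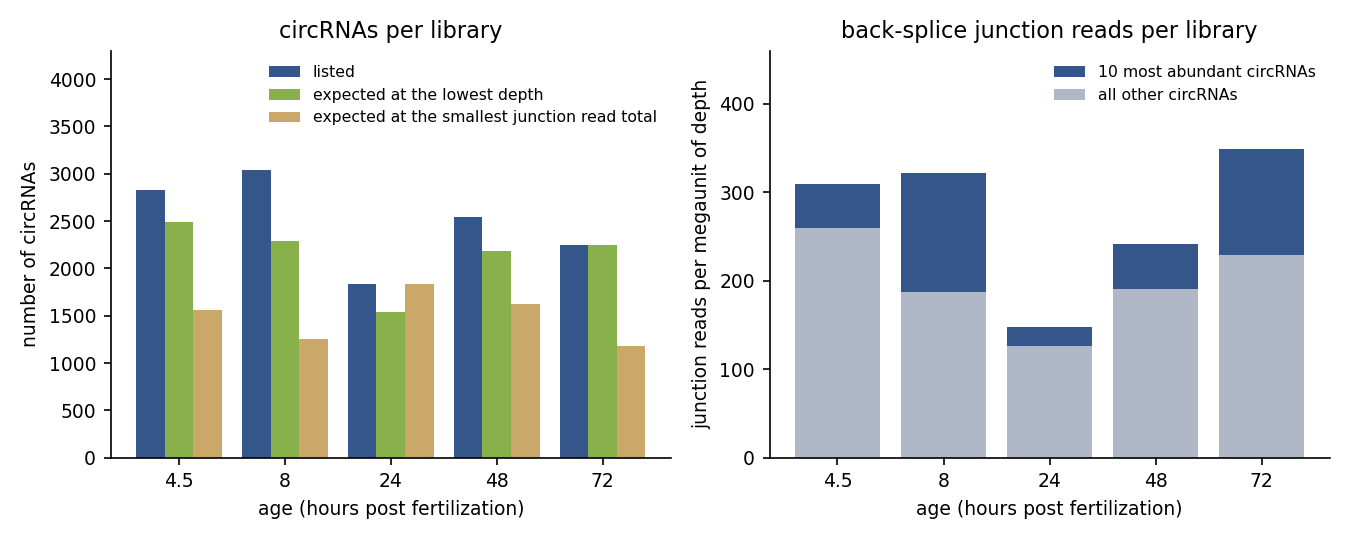
Left, the number of circRNAs per library (y axis) by age in hours post fertilization (x axis), listed, and expected at the lowest depth and at the smallest junction read total. Right, junction reads per megaunit of depth by age, with the 10 most abundant circRNAs of each library apart from all others; the 24 hpf library is lowest at 148.

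The most abundant circRNA differed between libraries, and in 4 of the 5 it was listed in only 1 library. At 4.5 hpf it lay on chromosome 22, 25714875 to 25722913, with 830 reads (4.07% of the library). At 8 hpf, the circRNAs of scaffold KN150127.1, 3657 to 4045 and 15984 to 16405, had 4398 and 4025 reads (17.9% and 16.4%), and the former was listed in all 5 libraries. At 24 hpf the first was on chromosome 5, 31690298 to 31707047, with 264 reads (2.76%). At 48 hpf it was on scaffold KN150127.1, 6486 to 9445, with 1275 reads (8.04%), ahead of chromosome 3, 18251099 to 18253055, with 804 reads (5.07%). At 72 hpf it was on chromosome 5, 31688205 to 31704934, with 1689 reads (8.87%).

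The median genomic span of the listed circRNAs was longest in the blastula library and shortest at 48 hpf. It was 8083 bp at 4.5 hpf (7527 to 8569), 6932 bp at 8 hpf (6419 to 7374), 6177 bp at 24 hpf (5694 to 6932), 4722 bp at 48 hpf (4412 to 5066) and 5208 bp at 72 hpf (4895 to 5574). Spans under 500 bp made up 11.8% of circRNAs at 48 hpf (10.6 to 13.1) and 8.62% at 24 hpf (7.37 to 9.99). Spans over 100 kb made up 4.28% at 4.5 hpf (3.56 to 5.09) and 3.18% at 48 hpf (2.53 to 3.94). Weighted by reads, the medians were 8432, 2373, 8931, 3542 and 10203 bp, with 72 hpf longest and 8 hpf shortest.

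Most circRNAs were listed at only 1 stage. Of the 9559, 7730 (80.9%) were listed in 1 library, 1117 in 2, 426 in 3, 165 in 4 and 121 in all 5. The 276 circRNAs with at least 20 reads in some library were spread over these classes, with 70 listed in 1 library only, 48 in 2, 50 in 3, 34 in 4 and 74 in all 5. Of the 70, 24 had a circRNA with a span within 5% of theirs at another position within 100 kb in another library, among them chromosome 10, 29964129 to 29964982, chromosome 4, 379926 to 384171, chromosome 19, 32902963 to 32910707, and chromosome 23, 3635683 to 3640895. Bounds for these circRNAs would not hold if 1 junction had been placed at different positions, which was not determined. Later stages shared more with each other than with the blastula. The Jaccard index, the number shared over the number listed in either library, was 0.135 for 48 and 72 hpf, 0.127 for 24 and 72 hpf, 0.124 for 4.5 and 8 hpf, and 0.0686 for 4.5 and 72 hpf. Of the 127 circRNAs with at least 20 reads at 4.5 hpf, 82.7% were listed at 8 hpf (75.0 to 88.8) and 74.0% at 24 hpf (65.5 to 81.4). The share was 56.7% at 48 hpf (47.6 to 65.5) and 61.4% at 72 hpf (52.4 to 69.9).

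**Figure D2:**
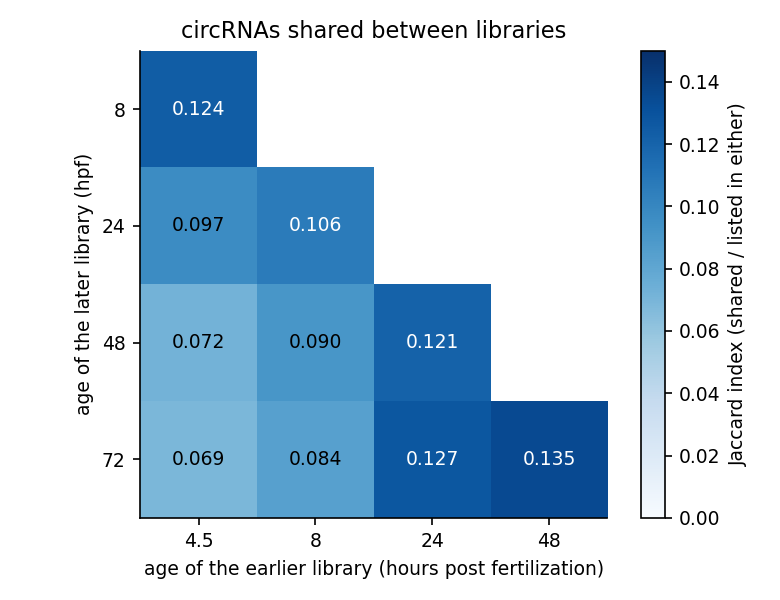
The Jaccard index of circRNAs listed in a pair of libraries, for the earlier library (x axis, age in hpf) and the later (y axis, age in hpf); darker cells share more. Values run from 0.0686 for 4.5 and 72 hpf to 0.135 for 48 and 72 hpf.

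Sets of stages in a run and sets with a gap both held circRNAs listed at no other stage. Sets with a gap included 8 and 48 hpf with 110 circRNAs, 4.5 and 24 hpf with 87, 24 and 72 hpf with 83, and 8 and 72 hpf with 74, against 81 for the run of 8 and 24 hpf and 83 for that of 24 and 48 hpf. The run from 24 to 72 hpf had 97 circRNAs, led by chromosome 5, 31666036 to 31700665, with 39, 123 and 408 reads at 24, 48 and 72 hpf. The circRNA of chromosome 19, 18954243 to 18955394, had 26, 50 and 53 reads at those stages, and that of chromosome 13, 1410993 to 1412348, had 9, 27 and 48. From 8 hpf onwards, 52 circRNAs were listed, among them chromosome 12, 47647969 to 47670672, with 17, 40, 60 and 73 reads, and chromosome 10, 44527274 to 44542314, with 6, 18, 64 and 53. At 4.5 and 8 hpf alone there were 283, including chromosome 10, 41368493 to 41374060, with 71 and 13 reads, and chromosome 15, 21583828 to 21599671, with 61 and 11. Another 75 were listed up to 24 hpf and no later, such as chromosome 15, 4242564 to 4251905, with 100, 22 and 5 reads, and chromosome 24, 9051933 to 9052722, with 65, 61 and 9. A further 190 were listed at 48 and 72 hpf alone, led by chromosome 9, 37683792 to 37695047, with 51 and 81 reads.

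Between blastula and gastrula, more circRNAs were lower than higher. Of 545 circRNAs with at least 10 reads over the 2 libraries, 111 were at least 2-fold higher at 8 hpf and 274 lower. The highest ratios were on chromosome 6, 6817343 to 6833488 (not listed, then 877 reads, at least 252-fold), and on scaffold KN150127.1. There, 15984 to 16405 was 193-fold higher (122 to 326) and 3657 to 4045 was 173-fold higher (114 to 276). A short circRNA of chromosome 1, 25967354 to 25967612, was at least 41.1-fold higher. The circRNA of chromosome 22, 25714875 to 25722913, was at least 320.5-fold lower, and on chromosome 19 those at 32902963 to 32910707 and 27980175 to 27985610 were at least 80.3-fold and 51.7-fold lower. That of chromosome 16, 32233692 to 32234165, went from 389 to 16 reads, 28.2-fold lower (17.1 to 49.8). On chromosome 16, 51147594 to 51230708, reads went from 74 to not listed, at least 28.6-fold lower. Of the 10 circRNAs named in each direction, 8 of the higher and 9 of the lower ratios were bounds. Of the calls, 28.8% were higher, and 39.3% with TMM scaling, which removes a shift of -0.54 on the log2 scale.

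Between gastrula and segmentation, scaffold KN150127.1 fell out of the signal and circRNAs of chromosomes 5, 3, 1 and 8 were higher. Of 386 circRNAs, 93 were higher at 24 hpf and 172 lower. On the scaffold, 15984 to 16405 was at least 1136-fold lower and 3657 to 4045 was 931-fold lower (363 to 3417). Chromosome 6, 6817343 to 6833488, was at least 247-fold lower, and chromosome 17, 3349985 to 3350375, went from 81 to 7 reads, 9.79-fold lower (4.54 to 25.1). On chromosome 5, 31690298 to 31707047 was at least 104-fold higher. On chromosome 3, 31968704 to 31994174 had 202 reads and was at least 79.6-fold higher. Chromosome 1, 58724086 to 58783408, was at least 46.9-fold higher with 119 reads. The circRNA of chromosome 8, 16656395 to 16668464, went from 5 to 95 reads, 22.4-fold higher (9.29 to 70.7). The split of calls depended on the scaling. Of the calls, 35.1% were higher per depth, but 71.3% (149 higher, 60 lower) when scaled to total junction reads, which removes a shift of -1.12 on the log2 scale; TMM removed -0.17. With that scaling to totals the bounds on the falls were smaller, with log2 ratios of -9.03 for 15984 to 16405 of the scaffold and -6.83 for chromosome 6, 6817343 to 6833488.

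**Figure D3:**
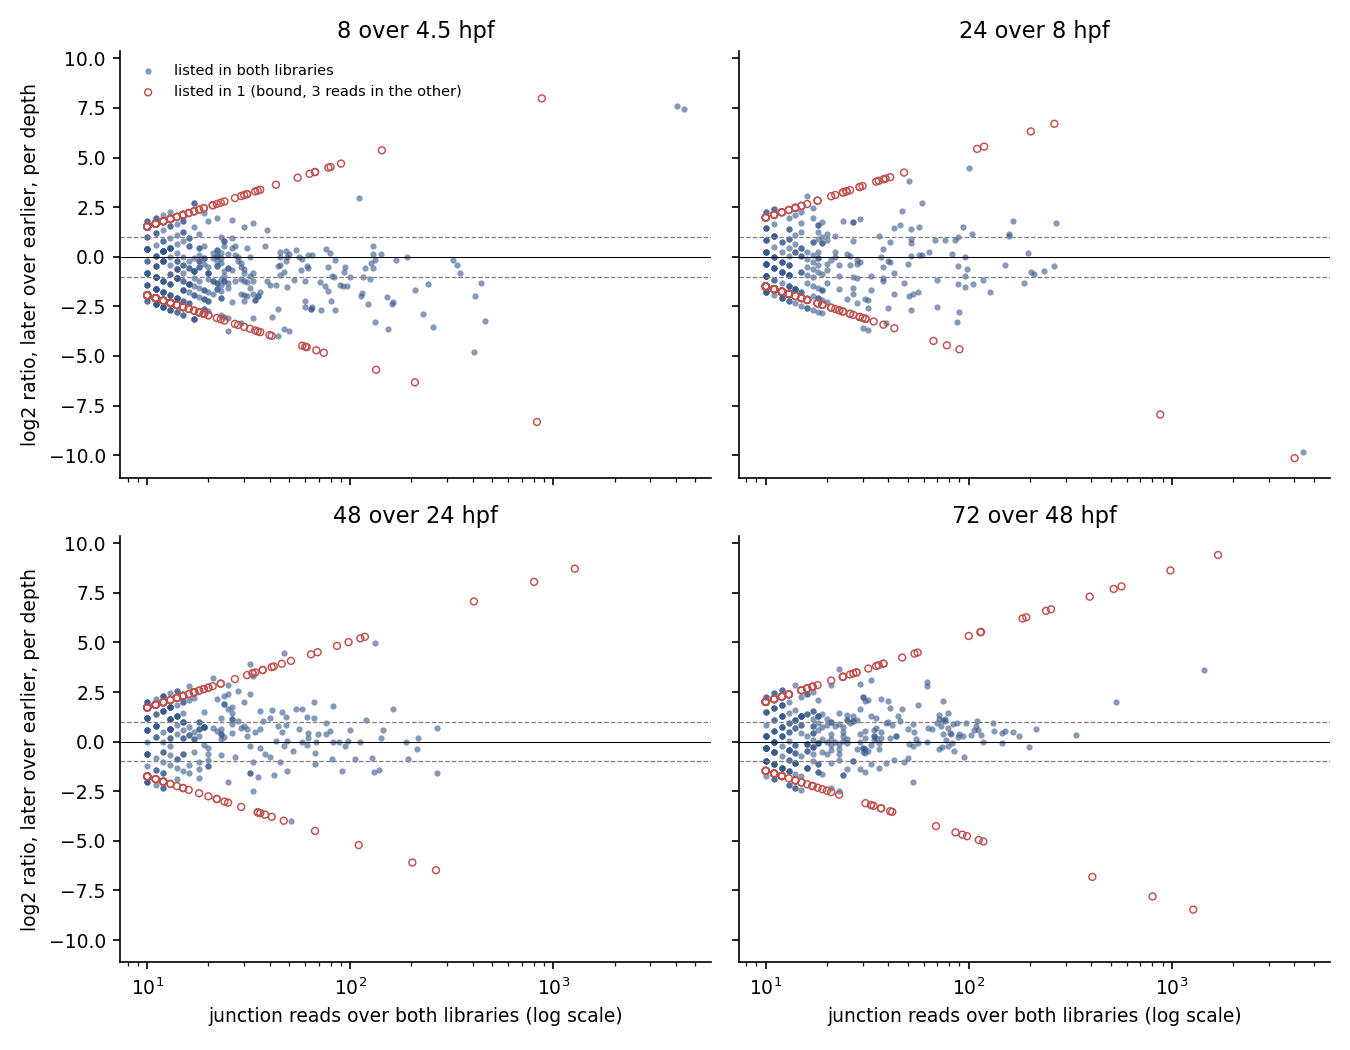
The log2 ratio of junction reads per depth, later over earlier (y axis), against the junction reads over both libraries (x axis, log scale), 1 point per circRNA with at least 10 reads, for the 4 consecutive pairs. Open points are bounds for circRNAs listed in 1 of the libraries, set at 3 reads in the other; dashed lines mark a ratio of 2 either way.

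Between 24 and 48 hpf, more circRNAs were higher than lower, 152 against 77 of 347. Scaffold KN150127.1 was again among the highest. There, 6486 to 9445, listed at 48 hpf only, was at least 420-fold higher (1275 reads), and 3657 to 4045 went from 4 to 129 reads, 31.9-fold higher (12.1 to 119). Chromosome 3, 18251099 to 18253055, was at least 265-fold higher, chromosome 10, 29964129 to 29964982, at least 134-fold, and chromosome 23, 3635683 to 3640895, at least 38.9-fold. Short circRNAs of chromosome 6, 39312756 to 39313067, and chromosome 19, 41413107 to 41413353, were at least 32.3-fold and 28.3-fold higher. On chromosome 5, 31690298 to 31707047 was at least 89.1-fold lower, and on chromosome 3, 31968704 to 31994174 at least 68.2-fold lower. The chromosome 5 bound holds for the exact position only, since the region around it had 327 reads at 24 hpf and 146 at 48 hpf. On chromosome 8, 16653399 to 16666779 had 47 reads at 24 hpf and was at least 15.9-fold lower at 48 hpf. Of the calls, 66.4% were higher per depth and 51.6% when scaled to total junction reads (112 higher, 105 lower), which removes a shift of 0.71 on the log2 scale. TMM removed 0.28. Without the 24 hpf library, 48 over 8 hpf gave 176 higher and 183 lower of 461.

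Between 48 and 72 hpf, 146 of 426 circRNAs were higher and 94 lower. The highest ratios were in 1 region of chromosome 5, where 31688205 to 31704934 was at least 677-fold higher and 31690705 to 31707442 at least 394-fold higher. Both had circRNAs of nearly the same span at shifted positions in another library, such as 31690298 to 31707047 at 24 hpf, so these bounds hold for the exact positions only. Scaffold KN150127.1, 3657 to 22829, was at least 226-fold higher with 565 reads. Chromosome 14, 3395835 to 3406037, was at least 207-fold higher, chromosome 4, 379926 to 384171, at least 158-fold, and chromosome 23, 35611270 to 35616264, at least 96.2-fold. Lower were scaffold KN150127.1, 6486 to 9445, by at least 354-fold, chromosome 3, 18251099 to 18253055, by at least 223-fold, and chromosome 10, 29964129 to 29964982, by at least 113-fold. The scaffold as a whole did not fall, with 1585 reads at 48 hpf and 1942 at 72 hpf. Its bound therefore holds for the exact position only. Of the 20 named circRNAs, 8 of the higher and 9 of the lower were listed in 1 library only. Of the calls, 60.8% were higher per depth, but 43.8% when scaled to total junction reads (98 higher, 126 lower), which removes a shift of 0.53 on the log2 scale. TMM removed 0.16.

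The 121 circRNAs listed in all 5 libraries had a median ratio of highest to lowest SRPBM of 4.70. Per depth, most were highest at the ends of the series, 55 at 4.5 hpf and 27 at 72 hpf. The stage of the peak was not counted under the other scalings. All junction reads per megaunit of depth were 309 at 4.5 hpf and 349 at 72 hpf, against 148 at 24 hpf. Scaling to total junction reads would therefore lower both ends of the series against 24 hpf. The steadiest of the 10 most abundant was on chromosome 11, 44020549 to 44026831, at 15.9 SRPBM at 4.5 hpf and 9.91 at 72 hpf, a 1.60-fold range (1.22 to 2.12). On chromosome 25, 32356968 to 32384589 had its lowest level at 8 hpf (4.79 SRPBM) and its highest at 72 hpf (20.9). Highest at 4.5 hpf were chromosome 2, 57502503 to 57945198 (41.6 SRPBM, 21.3-fold range, 13.4 to 35.7), chromosome 16, 32233692 to 32234165 (39.3 SRPBM, 64.2-fold, 27.3 to 199), and chromosome 16, 55075739 to 55381521 (32.1 SRPBM, 5.38-fold, 4.05 to 7.24). Also highest at 4.5 hpf were chromosome 2, 116705 to 117894 (30.2 SRPBM), chromosome 17, 48844580 to 48934121 (21.1), and chromosome 1, 53451167 to 53519640 (18.2). Chromosome 11, 43496943 to 43559737, peaked at 24 hpf with 20.4 SRPBM. Levels fell at each step for 8 circRNAs, such as chromosome 7, 15515797 to 15533024, with 231, 23, 10, 9 and 3 reads. They rose at each step for 2. These were chromosome 25, 49041 to 75416, with 9, 13, 33, 43 and 47 reads, and chromosome 4, 15943320 to 15945117, with 3, 6, 6, 19 and 18. Steps were counted on SRPBM with no minimum size, so some are no larger than counting error.

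**Figure D4:**
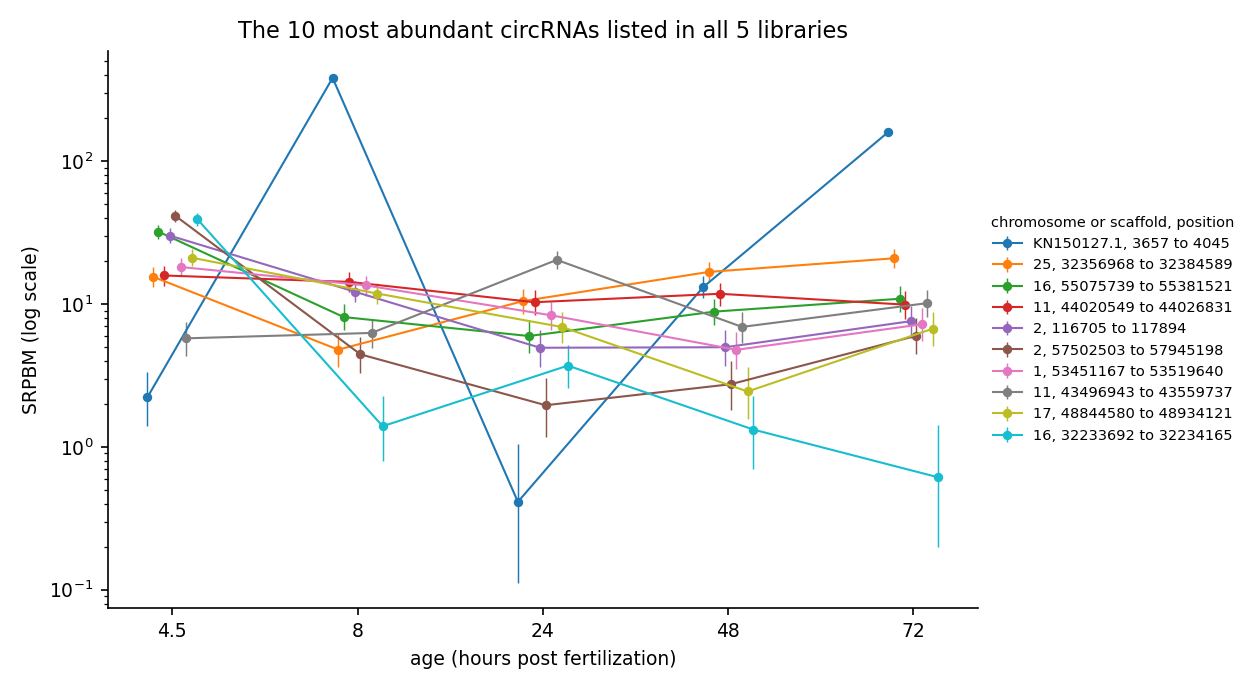
SRPBM (y axis, log scale) by age in hours post fertilization (x axis) of the 10 circRNAs with the highest mean SRPBM among those listed in all 5 libraries, with exact Poisson 95% intervals that cover counting error only. The circRNA of scaffold KN150127.1 ranges 931-fold, that of chromosome 11, 44020549 to 44026831, 1.60-fold.

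A pair of regions held the largest shares of junction reads, and both differed between stages. Scaffold KN150127.1, with 10 circRNAs, held 34.4% of the reads at 8 hpf (33.8 to 35.0), 10% at 48 hpf and 10.2% at 72 hpf, but 0.196% at 4.5 hpf and 0.0732% at 24 hpf. The region of chromosome 5, 31666036 to 31708780, was not listed at 4.5 and 8 hpf and held 3.42% of the reads at 24 hpf (3.06 to 3.803), 0.921% at 48 hpf and 16.7% at 72 hpf (16.2 to 17.2). Of its 9 circRNAs, 8 were listed in 1 library only. Their spans fell into a pair of sizes, 7 between 16001 and 17825 bp and 2 of 34544 and 34630 bp. Whether these are separate circRNAs or fewer junctions placed at shifted positions was not determined. In contrast, the region of chromosome 25, 32356968 to 32393794, had reads at every stage, 240, 85, 168, 243 and 263.

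**Figure D5:**
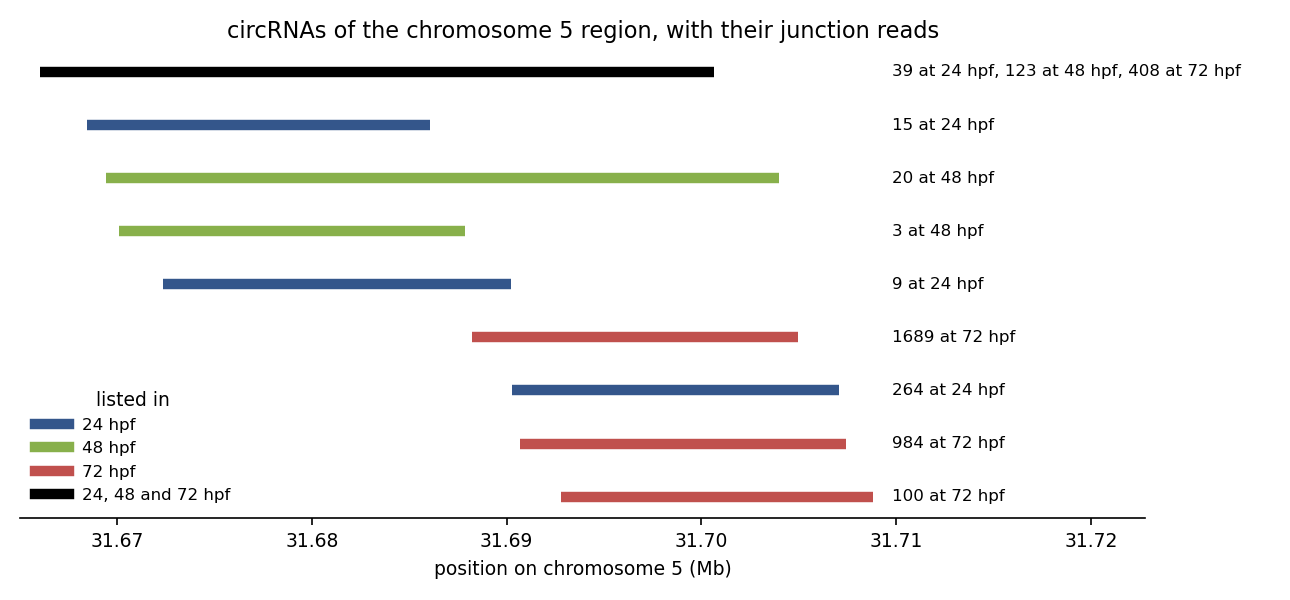
The 9 circRNAs of the chromosome 5 region as bars from start to end (x axis, position in Mb), coloured by the libraries that list them, with their junction reads at the right. Only that at 31666036 to 31700665 is listed in more than 1 library.

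Some circRNAs shared a start or an end position with another circRNA of the same library. They made up 17.4% of circRNAs at 4.5 hpf (16.0 to 18.8) and 18.6% at 8 hpf (17.3 to 20.05). The shares were 11.2% at 24 hpf (9.82 to 12.8), 10.95% at 48 hpf (9.77 to 12.2) and 11.1% at 72 hpf (9.83 to 12.5). Whether shared positions reflect alternative back-splicing was not tested. At equal numbers of circRNAs per library (1834, drawn at random 200 times), the mean shares were 12.3% at 4.5 hpf (central 95% of draws 10.5 to 13.7), 12.3% at 8 hpf (10.4 to 14.1), 11.2% at 24 hpf, 8.11% at 48 hpf (6.98 to 9.43) and 9.20% at 72 hpf (8.12 to 10.2). The 3 earlier libraries then differed little from each other, and the 2 later ones were lower. Pooled over the 5 libraries, the start used by most circRNAs was on chromosome 1 at 57867011, with 9 circRNAs and 77 reads, 47 of them at 4.5 hpf. On chromosome 3, the end at 62102688 was used by 7 circRNAs with 106 reads, 52 of them at 4.5 hpf. The end on chromosome 1 at 28005792 had 5 circRNAs with 39, 24, 20, 43 and 56 reads from 4.5 to 72 hpf. Among circRNAs with at least 5 reads, the shares were lower, at 9.86%, 11.6%, 7.63%, 4.26% and 7.03% from 4.5 to 72 hpf.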

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

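The values at equal depth, without the 24 hpf library, without scaffold KN150127.1, for 48 over 8 hpf and for shared ends were chosen after the data were seen. With at least 5 reads, 933, 801, 367, 658 and 555 circRNAs were listed at 4.5, 8, 24, 48 and 72 hpf, 63 of them in all 5 libraries where each library had to reach 5, and the series table, which holds only circRNAs listed in at least 2 libraries, gave 943, 1080, 879, 974 and 901. At the smallest junction read total, 1563.1, 1252.9, 1623.8 and 1178.8 were expected at 4.5, 8, 48 and 72 hpf. Weighted by reads, the median span was 2373, 8931, 3542 and 10203 bp at 8, 24, 48 and 72 hpf, and with at least 5 reads it was 7384 and 4324 bp at 8 and 48 hpf. With at least 20 reads over both libraries, the calls numbered 32 higher and 111 lower at 8 over 4.5 hpf, 42 and 60 at 24 over 8, 60 and 33 at 48 over 24, and 68 and 33 at 72 over 48; a ratio of 4 gave 50 and 146, 50 and 70, 75 and 37, and 86 and 36. Both rules admit fewer circRNAs by construction. Scaled to total junction reads, which removes a shift of -1.12 on the log2 scale, 24 over 8 hpf gave 149 higher and 60 lower. TMM, which removed -0.17, gave 100 and 168. Scaffold KN150127.1, with 34.4% of the reads at 8 hpf and 0.0732% at 24 hpf, made up part of that shift. What else lay behind it was not tested. An interval that excludes 1 can only remove calls, and left 60 of 94 lower at 72 over 48 hpf. Shared ends fell to 9.86%, 11.6%, 7.63%, 4.26% and 7.03% from 4.5 to 72 hpf with at least 5 reads, where fewer circRNAs can share. At equal numbers of circRNAs they were 12.3%, 12.3%, 8.11% and 9.20% at 4.5, 8, 48 and 72 hpf, and at equal junction read totals 12.002%, 11.7%, 8.34% and 7.39%, against 11.2% at 24 hpf, so most of the gap between 24 hpf and the earlier stages closed. The other 43 values stayed within 1.5 times or within their interval, among them the counts without scaffold KN150127.1 and the expected numbers at equal depth. Comparing 48 with 8 hpf directly, 176 were higher and 183 lower, and 136 circRNAs were listed in the 4 libraries other than 24 hpf. Among the named circRNAs, 151 ratios under the other scalings stayed within their intervals and 9 moved, all of them falls from 8 to 24 hpf scaled to total junction reads, whose log2 ratios were then 1.12 nearer to 0. These circRNAs were chosen for extreme ratios, so a change of direction was not possible under these scalings. Most of the ratios were bounds, whose intervals were very wide on the side away from 1. For chromosome 6, 6817343 to 6833488, at 8 over 4.5 hpf, the interval was 135.53 to 29937.5. A shift away from 1 under these scalings could not leave such an interval, so the 151 say little about stability. Not run, for want of an annotation of the build, were host genes in place of circRNAs, host gene lists, genomic class, junction bases and circRNAs per host gene. No paired analysis was possible because each stage had 1 library. The lowest listed count of 2 reads limits what can be said of any circRNA that is not listed, and the bounds assume that too few reads were the reason.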

Other observations

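The tests of long spans and of the order of the stages were chosen after the result was seen, and the regions described here were picked after their values were seen.

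Several regions differed in reads between stages as a whole. On chromosome 8, 16653399 to 16676388, 6 circRNAs had 7 and 9 reads at 4.5 and 8 hpf, then 157, 94 and 133 from 24 hpf on. On chromosome 3, 31968704 to 32008945, 5 circRNAs had 36 reads at 8 hpf, 205 at 24 hpf, none listed at 48 hpf and 275 at 72 hpf. Early regions were found on chromosome 7, 35393916 to 35421152, where 8 circRNAs had 19 and 21 reads at 4.5 and 8 hpf and none were listed later, and on chromosome 1, 48881262 to 48904509, where 7 circRNAs had 55 and 4.

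The chromosomes differed in how densely they carried circRNAs. Chromosome 4 had the fewest, 3.92 per Mb up to its last listed position, and chromosome 22 the most, 9.29 per Mb. The region with most circRNAs nevertheless lay on chromosome 4, 76321360 to 76325481, where 25 circRNAs with a median span of 522 bp had 12, 169, 17, 74 and 2 reads from 4.5 to 72 hpf.

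The segmentation library had the fewest circRNAs and junction reads. At equal depth, the lowest of the other 4 libraries still listed 1.41 times as many circRNAs, which argues against depth, and without the 10 most abundant circRNAs of each library the lowest of the others had 1.49 times the reads per depth, which argues against a few dominant circRNAs. An even loss of circRNA reads was also examined. The 135 circRNAs listed in the other 4 libraries, scaffold KN150127.1 left out, stood at 1.02 times the mean of 8 and 48 hpf (bootstrap 95% interval 0.868 to 1.19). The remaining reads stood at 0.607. This difference cannot decide the question, because most of the remaining circRNAs had few reads. An even loss would take more of them below the lowest listed count of 2 reads. The typical circRNA was still lower at 24 hpf. Among circRNAs with at least 10 reads over a pair of libraries and listed in both, the median ratio was 0.788 for 24 over 8 hpf and 1.48 for 48 over 24 hpf. An even loss is therefore not excluded. The shortfall at 24 hpf lay more in circRNAs with several reads than in those with fewest. Those at exactly 2 reads numbered 895 at 24 hpf and 897, 1165, 1032 and 949 at 4.5, 8, 48 and 72 hpf. Those with at least 5 reads numbered 367 against 933, 801, 658 and 555. A feature of the stage and a feature of this library preparation remain open, and neither was tested.

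Sampling at a constant level gave at most 0 circRNAs listed in 1 library only with 20 reads or more in 100 draws, against 70 observed, which argues against counting chance alone. It says nothing of variation between libraries of a stage, which has no replicate. A candidate explanation is a repeated sequence whose junction is placed at shifted positions in different libraries. Of the 70, 34.3% (24, exact 95% interval 23.3 to 46.6) had a circRNA of nearly the same span within 100 kb in another library, against 16.5% of 206 abundant circRNAs listed in more libraries, which had a near-copy in any library. The value lies between the bounds set for and against it, so repeats and stage-specific circRNAs cannot be told apart for these 70 without the genome sequence.

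Spans over 100 kb made up 14.0% (17 of 121) of the circRNAs listed in all 5 libraries and 3.49% of all. Abundance may account for part of this but did not account for all of it. Draws of other circRNAs matched on total reads had a median of 6.61%, above the 3.49% of all circRNAs. The draws gave 2.48 to 11.6%, and the observed 14.0% lay somewhat above that. Of those 17, 58.8% (10) lay within 2 Mb of the first or last listed position of a chromosome, against 14.8% of 317 other long circRNAs (2-sided Fisher's exact test, p = 7.4748e-05, over circRNAs, which are not replicates). A candidate explanation is sequence placed out of order in the assembly near chromosome ends, so that ordinary splicing reads as back-splicing. No biological explanation was tested, and the design names none that applies.

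The hypothesis that the overlap follows the order of the stages was tested. The mean Jaccard index over consecutive pairs was 0.122 in the real order, and 2 of the 60 orders of the libraries, the real one included, reached it (exact permutation p = 0.0333, 1-sided). The highest other order had 0.123, so the real order was near the top without leading.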
